A study of Danio rerio with 4 samples.

How the data were processed

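Droplet single-cell RNA sequencing was performed on dissociated zebrafish heads, wild type or sp7 mutant, in 4 libraries, 1 for each of 2 genotypes and 2 labelled lengths. The deposited values are raw UMI counts per gene and cell barcode, with 32522 features including the eGFP and mCherry sequences. According to the submitters' processing notes the counts were made with Cell Ranger 3.1.0 on genome build danRer11. Every listed barcode had at least 500 UMIs. The 568 symbols found on several features (3956 features) were kept apart by identifier. Genotype, length and age were taken from the labels. File names give both libraries of a labelled length the same tag, so that stage and preparation cannot be separated.

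Cells with at least 200 genes and at most 20% mitochondrial UMIs were kept, 4454, 5898, 13032 and 12911 of 5738, 7287, 14687 and 15934 barcodes (wild type 5.8 mm, mutant 5.8 mm, wild type 7.0 mm, mutant 7.0 mm). Scrublet, run in scanpy 1.11.5, marked 6 cells at its automatic threshold. In its place, after this was seen, the cells with the highest scores were removed at 0.8% per 1000 barcodes, which took 204, 344, 1531 and 1646 cells. The 32570 kept cells held 22469738, 23474387, 32817996 and 32209709 UMIs. Counts were normalised and log-transformed, and 2000 variable genes, 40 principal components, 20 neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 gave 42 clusters. No integration across libraries was made. The variable genes left out sp7, the transgenes and the lists for bone matrix, osteoblast transcription factors and collagen I, so that these genes do not place the cells. Other genes that differ between the genotypes can still do so. A cluster took the name of a class when at least 3 of its markers stood among its top 50 genes and at least 2 times as many as for the next class, provided that no other class had more markers among the top 10. Top genes were ranked by the fold of CPM over all other cells with 5 CPM added, among genes seen in at least 10% of the cluster's cells. This named 15 classes and left 19 clusters unnamed. The condition on the top 10 was added after a cluster with grn2, spic and il1fma was seen, which stayed unnamed. Osteoblast-like cells are cluster 24, chondrocyte-like cells cluster 34 and fibroblast-like cells clusters 0, 3 and 4. Class names rest on marker genes only.

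UMIs were summed for each library and class. Genes were tested in edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr and the quasi-likelihood F test, with stage and genotype as terms. This left 1 residual degree of freedom and treats a difference of the genotype effect between stages as error. Adjusted p is by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. Standard errors of edgeR values were calculated back from the test, as the absolute log2 fold change divided by the square root of F. With 1 library for each genotype and stage there was no test within a stage. There, sums of counts are given as CPM with exact Poisson 95% intervals and the ratio with its interval, and class shares with exact Clopper-Pearson 95% intervals. These cover counting error only. A gene at 0 UMIs in a library was set against a floor of 3 UMIs. Shares of cells with a UMI were taken after thinning each cell with enough UMIs to 1000 UMIs, and also without thinning. Medians of gene lists were ranked among 10000 random lists drawn from the 100 nearest genes in expression. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, statsmodels 0.14.6, matplotlib 3.10.9 and DESeq2 1.42.0.

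The test was checked on simulated data, where folds of 2, 4 or 8 were given to 200 genes in negative binomial counts with the dispersions estimated for each class. In osteoblast-like cells 8.33%, 77.4% and 100.0% of the changed genes were recovered with 1 false call, and in chondrocyte-like cells 6.35%, 57.6% and 95.3% with 3. In fibroblast-like cells 18.8%, 92.2% and 100.0% were recovered with 8 false calls, and over all cells 26.9%, 82.8% and 98.5% with 7. The simulated genotype effect was the same at both stages, and the counts came from the model of the test. Recovery and false calls are therefore not covered where effects differ between stages or the make-up of a class shifts.

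Comparisons, tests, class markers, the 19 gene lists and the rule for named genes were fixed before the data were examined. The rule names sp7 and the transgenes always. For each genotype effect it names the 10 genes in each direction with the largest fitted change among those that passed, moved alike in both stages and had at least 50 UMIs in the higher genotype at each stage. Missing places were filled by the size of the smaller ratio and are given as values that did not pass. For each stage effect it names 5 in each direction, and up to 4 members of each list. Of the list members and of the places filled by size the text gives a part. Genes known by a clone name only are counted but not named. Called genes outside this rule (scpp7, scpp1, igfbp3, timp2b and lgals2a among them, the globin, heat shock and organ genes, and the genes of the other classes) were chosen after their values were seen. The lists cover osteoblast transcription factors, bone matrix and mineralization, collagen I synthesis, osteocyte, cartilage matrix, hypertrophic cartilage, osteoclast, tendon and ligament, tooth, WNT, BMP, hedgehog and FGF response, cell cycle, dissociation stress, endoplasmic reticulum stress, inflammation, matrix remodelling and hemoglobin. The alternatives fixed beforehand were RLE size factors, DESeq2, no filter on low counts, 1 term only, leaving out each library in turn, at least 500 genes and at most 10% mitochondrial UMIs, doublets kept, Leiden resolution 2, the bone lists among the variable genes (for class shares), TMM-scaled CPM and no thinning. Added after the data were seen were fits without erythrocyte-like cells, classes from other variable genes, fibroblast-like cells outside cluster 4, and DESeq2 and 1-term fits for the other classes. Reads, alignment and intronic counts were not analysed here.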

Results

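Single-cell transcriptomes were recorded from zebrafish heads after brain and eyes had been taken out. The design crossed 2 genotypes, wild type and sp7 mutant, with 2 labelled lengths, 5.8 mm (2 weeks) and 7.0 mm (3 weeks), with 1 library for each of the 4 combinations. Sp7 is a zinc finger transcription factor of bone-forming cells. All fish carried an enhancer reporter near bmper driving eGFP and an sp7 reporter driving mCherry. Values below are given in the order wild type 5.8 mm, mutant 5.8 mm, wild type 7.0 mm, mutant 7.0 mm. The libraries held 5738, 7287, 14687 and 15934 barcodes with 26609950, 27666173, 44292404 and 45564182 UMIs. After filtering, 4250, 5554, 11501 and 11265 cells remained, with median depths of 2102, 2272.5, 1841 and 1937 UMIs per cell. The labels do not give the number of fish per library or whether fish were pooled. No combination was repeated, so the p-values rest on how an effect differs between these libraries and on dispersions shared across genes. They do not measure the spread between like libraries or between fish.

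The targeted gene was examined first. In osteoblast-like cells, sp7 was counted at 16, 97, 208 and 325 UMIs, or 172, 410.4, 472 and 524 CPM (UMIs of a gene scaled to the UMIs of the class in that library). The mutant to wild-type ratio was 2.38 (95% interval 1.39 to 4.33) at 5.8 mm and 1.11 (0.929 to 1.33) at 7.0 mm, intervals that cover counting error only. Across both stages the edgeR log2 fold change was 0.47 with a standard error of 0.47 and an adjusted p of 0.999. Transcripts of sp7 were thus still counted in both mutant libraries. The labels do not describe the allele, so this count does not check which library is mutant. After thinning to 1000 UMIs per cell, 11.1%, 42.9%, 39.7% and 43.3% of osteoblast-like cells had an sp7 UMI, against 0%, 0%, 0% and 0.176% of erythrocyte-like cells. Without thinning the shares were 42.1%, 71.4%, 59.3% and 70.202%, against 0%, 0%, 0% and 0.145%. Median depths were 4723, 3879, 2846 and 2775.5 UMIs in osteoblast-like cells and 4379.5, 2460, 2382 and 2398 in erythrocyte-like cells.

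The eGFP reporter rose in mutant osteoblast-like cells. It was counted at 43.1, 1637, 795 and 2897 CPM, from 4, 387, 350 and 1798 UMIs. The mutant to wild-type ratio was 38.0 (14.7 to 140) at 5.8 mm and 3.64 (3.25 to 4.10) at 7.0 mm. The 4 wild-type UMIs at 5.8 mm all lay in the same cell, 5.26% of 19, and the interval there treats them as independent. The log2 fold change across stages was 2.86 with a standard error of 0.60 and an adjusted p of 0.0337. Endogenous bmper, a secreted regulator of bone morphogenetic proteins, had 5, 21, 24 and 43 UMIs in these cells, or 53.9, 88.8, 54.5 and 69.3 CPM. After thinning, 5.56%, 45.2%, 21.4% and 63.9% of osteoblast-like cells had an eGFP UMI, against 0%, 0%, 0.467% and 0.527% of erythrocyte-like cells. Without thinning the shares were 5.26%, 49.0%, 32.9% and 71.7%, against 0%, 0%, 0.585% and 0.435%. The mCherry reporter stood at 9742.5, 6896, 6366 and 6389 CPM and did not pass the test, with a log2 fold change of -0.41, a standard error of 0.51 and an adjusted p of 0.999. Without the wild-type library labelled 5.8 mm its log2 fold change was 0.20, in a fit where stage and genotype are no longer balanced. Of the mCherry UMIs, 95.7%, 96.2%, 84.5% and 86.5% lay in osteoblast-like cells. Of the alternatives tried, 4 of 12 called eGFP, with adjusted p from 4.9e-07 to 1.00, and its log2 fold change was positive in each of them.

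Osteoblast-like cells made up a larger share of the kept cells in the mutant library of each stage. The shares were 0.447% (19 cells, exact Clopper-Pearson 95% interval 0.269 to 0.697), 0.882% (49 cells, 0.653 to 1.16), 1.22% (140 cells, 1.02 to 1.43) and 1.76% (198 cells, 1.52 to 2.02). The mutant to wild-type ratio was 1.97 (1.14 to 3.55) at 5.8 mm and 1.44 (1.16 to 1.81) at 7.0 mm. Chondrocyte-like cells stood at 0.165%, 0.756%, 0.861% and 0.763%, so that only the wild-type library labelled 5.8 mm, with 7 such cells, lay apart. Their ratio of 4.59 at 5.8 mm was 1.62 with the bone genes among the clustering genes, and 2.68 (1.51 to 5.00) at Leiden resolution 2, each for a larger set of cells. In both, the cluster of these cells was unchanged at 7, 42, 99 and 86. With the bone genes a cluster of 1471 cells led by coch and col9a1b and another of 99 cells also took the name, and at resolution 2 clusters of 345 and 96 cells did. Fibroblast-like cells were named from connective tissue markers, and their cluster 3 also had the tendon marker tnmd among its leading genes. They stood at 8.47%, 11.0%, 24.9% and 26.7%. These shares were not tested between libraries, and the intervals cover counting error only.

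**Figure D1:**
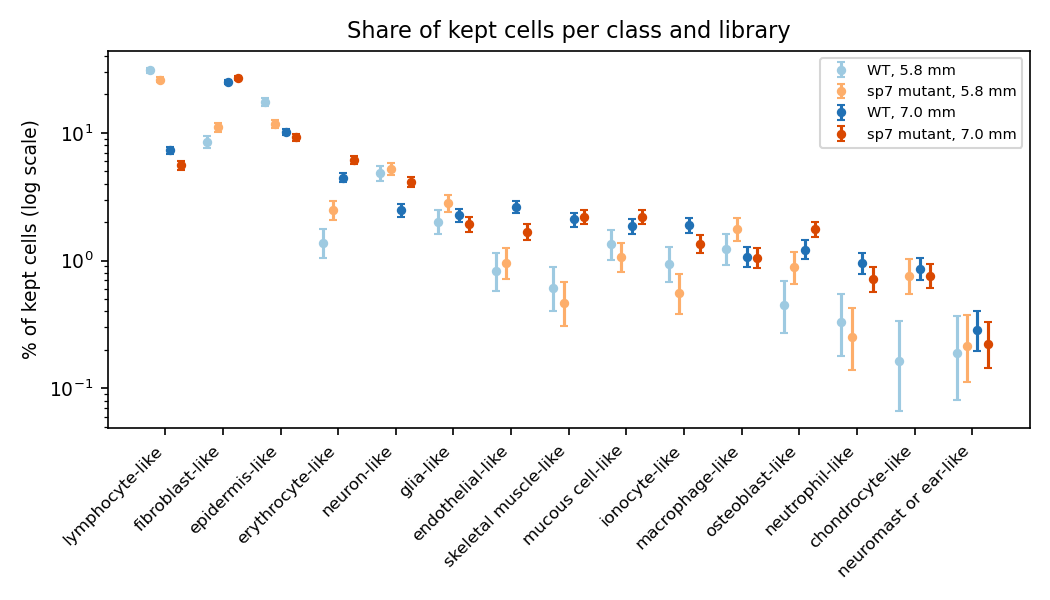
Percent of kept cells in each named class (log scale) for the 4 libraries, with exact Clopper-Pearson 95% intervals that cover counting error only. The osteoblast-like share was 0.447% and 0.882% at 5.8 mm, and 1.22% and 1.76% at 7.0 mm, in wild type and mutant.

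Shares of several classes differed between the stage labels, without a test, and the immune classes did not move alike. Neutrophil-like cells stood at 0.329%, 0.252%, 0.956% and 0.719%, and macrophage-like cells at 1.22%, 1.76%, 1.07% and 1.05%. Lymphocyte-like cells made up 30.8% and 26.0% of the cells in the libraries labelled 5.8 mm, against 7.28% and 5.56% in those labelled 7.0 mm. Epidermis-like cells stood at 17.4%, 11.7%, 10.2% and 9.19%, and skeletal muscle-like cells at 0.612%, 0.468%, 2.095% and 2.20%. Neuron-like cells stood at 4.80%, 5.203%, 2.48% and 4.11%, and endothelial-like cells at 0.824%, 0.954%, 2.63% and 1.68%. Between 29.2% and 35.6% of the cells of a library lay in clusters without a name.

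In osteoblast-like cells the comparison of sp7 mutant with wild type asks which genes of bone-forming cells depend on Sp7. The transcript of enam, which encodes an enamel matrix protein of the secretory calcium-binding family, was not detected in either mutant library. It was counted at 554, 0, 1623 and 0 UMIs, or 5970.5, 0, 3686 and 0 CPM. Against a floor of 3 UMIs per library it was at least 470.4-fold lower at 5.8 mm and at least 763-fold lower at 7.0 mm, with an adjusted p of 4.0e-08. Its relative scpp7 fell as well, from 7 and 70 UMIs in the wild-type libraries to 0 and 0. That is at least 5.94-fold and at least 32.9-fold, with an adjusted p of 5.4e-05. After thinning, 38.9%, 0%, 39.7% and 0% of the osteoblast-like cells had an enam UMI, where the 0 of 42 and 0 of 180 mutant cells allow shares of cells with an enam UMI at that depth of up to 7.14% and 1.67%. This does not limit the share of cells that express enam at a low level. The corresponding shares of erythrocyte-like cells were 0%, 0%, 0.234% and 0.176%. Without thinning, 36.8% and 40.0% of the wild-type cells had an enam UMI. In epidermis-like cells enam was still counted in the mutants, at 6.61, 7.60, 58.8 and 104 CPM.

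Further genes passed the test as lower in mutant osteoblast-like cells, but none of them stayed called at Leiden resolution 2. There the class held 199 in place of 198 cells of the mutant labelled 7.0 mm, and the same numbers in the other libraries. Another member of the secretory calcium-binding family, scpp1, fell by 2.58 on the log2 scale (standard error 0.48, adjusted p = 0.0179), with 33, 21, 100 and 20 UMIs. The network collagen gene col10a1b fell by 2.54 (standard error 0.51, adjusted p = 0.0235), with 123, 110, 337 and 49 UMIs. It was 2.85-fold lower at 5.8 mm and 9.69-fold lower at 7.0 mm. The secreted insulin-like growth factor binding protein gene igfbp3 fell by 2.50 (standard error 0.48, adjusted p = 0.0182). The metalloproteinase inhibitor gene timp2b fell by 2.61 (standard error 0.55, adjusted p = 0.0337), and the galectin gene lgals2a fell by 2.50 (standard error 0.55, adjusted p = 0.0464). Altogether 1 gene, eGFP, rose and 8 genes fell among 2675 tested, all 9 in the same direction in both stages. One of the 8 is known by a clone name only. At an unadjusted p under 0.05 there were 130 genes, no more than the share of 0.05 expected with no effect.

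Among genes that did not pass the test, the largest ratios repeated in both stages were as follows. The phosphoprotein gene spp1 had 481, 128, 239 and 207 UMIs, a log2 fold change of -2.14 and an adjusted p of 0.253. The fibrillar collagen gene col11a1b stood at -2.01 with an adjusted p of 0.0782. The collagen I chains had lower CPM in the mutant of each stage, with log2 fold changes of -1.06 for col1a1a and -1.05 for col1a2, and neither passed. Without the wild-type library labelled 5.8 mm, col1a2 stood at 0.0191. On the higher side stood the opioid precursor gene penkb (2.45, adjusted p = 0.132), the heparin-binding growth factor gene mdka (2.47, adjusted p = 0.114), fibina (1.87), nme2b.2 (1.70), and fgfbp2a (1.25). The homeobox gene dlx5a, an early osteoblast regulator, stood at 1.32 with 4, 78, 101 and 237 UMIs. The chromatin genes hmgn2 and h2afvb and the peroxiredoxin gene prdx2 stood at 1.02, 0.75 and 0.55. Lower values that did not pass were also seen for col11a2, hsp70l, ubb and dnajb1b, from -0.69 to -1.06. Of 12 alternatives, penkb and col11a1b were called in 5 and mdka in 4. Among the genes that passed, enam was called in 11, scpp7 in 10 of 11, igfbp3 in 5, scpp1 and lgals2a in 4, and timp2b and col10a1b in 3. Of the genes named here, col10a1b, spp1, col1a1a, col1a2 and dlx5a are also among the markers used to name the osteoblast-like class.

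The lists fixed in advance gave the following counts in osteoblast-like cells. For bone matrix and mineralization, 2 of 16 tested genes fell (scpp1 and col10a1b), and 3 when adjusted over the list alone. The median log2 ratio was 0.14 at 5.8 mm (-0.18 with TMM-scaled CPM, a changed sign) and -0.44 at 7.0 mm, where the median of all tested genes was 0.33 and -0.00. These lay at percentiles 48.0 and 0.0200 of 10000 random lists matched on expression. For collagen I synthesis, 0 of 21 genes were called by edgeR, and 2 fell when adjusted over the list alone. The medians of -0.30 (-0.62 with TMM-scaled CPM) and -0.50 lay at percentiles 0.170 and 0.00. The dissociation stress list lay as low at 7.0 mm, with 19 of 22 genes lower, a median of -0.43 and percentile 0.00. For the tooth list, 2 of 4 genes fell (enam and scpp1), and likewise 2 when adjusted over the list alone, with medians of -0.66 and -1.46 at percentiles 1.39 and 0.0300. For osteoblast transcription factors, none of 11 genes passed, nor any when adjusted over the list alone. Their medians were 0.97 at 5.8 mm, 0.69 with members at 0 set to their bound, and -0.04 at 7.0 mm. Hypertrophic cartilage had 1 of 9 lower (col10a1b), and 1 when adjusted over the list alone, with medians of 0.53 and -0.22. Cartilage matrix had 0 of 6 called and 1 lower when adjusted over the list alone, with medians of 0.30 and -0.50 at percentiles 61.1 and 0.770. Tendon and ligament had 0 of 4 called and 2 lower when adjusted over the list alone, with medians of -0.09 and -0.87 at percentiles 23.8 and 0.380. Of the osteocyte list only 2 genes could be tested, and of the osteoclast list 1, so that no median was formed.

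Signalling and cell state lists showed no call by edgeR, either over all genes or adjusted over the list alone, with 1 exception. The exception was matrix remodelling, where 1 of 7 genes fell (timp2b), also when adjusted over the list alone, with medians of -0.22 and -0.27. The 7 testable cell cycle genes had medians of 1.59 at 5.8 mm, 0.53 with members at 0 set to their bound, and 0.72 at 7.0 mm, at percentiles 99.5 and 100.0. WNT response (6 genes) had medians of 0.91 and 0.37. BMP response and antagonists (11 genes) had -0.62 and -0.20, at percentiles 0.200 and 13.8, with 8 of 11 genes lower at 5.8 mm. Hedgehog response (5 genes) had 0.85 and 0.01, at percentiles 82.3 and 59.4. FGF response (8 genes) had -0.12 and -0.69, at percentiles 14.1 and 0.380. Low percentiles were thus not particular to the bone matrix and collagen I lists. Dissociation stress (22 genes) had -0.03 and -0.43, at percentiles 21.5 and 0.00, and endoplasmic reticulum stress (12 genes) 0.26 and -0.36, at percentiles 41.0 and 0.850. Inflammation (3 genes) had -0.90 and -0.00. Hemoglobin (6 genes) had -0.36, or -0.73 with members at 0 set to their bound, and 0.60. These are values that did not pass the test.

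Of the 9 calls in osteoblast-like cells, only enam and scpp7 were kept with RLE size factors, where 0 genes rose and 2 fell, against 1 and 8 with TMM. Leiden resolution 2 kept the same 2 genes, with 199 in place of 198 cells of the mutant labelled 7.0 mm. The other calls, eGFP included, thus did not outlast a very small change of the class. DESeq2 called 3 genes, of which col10a1b and igfbp3 were shared, and gave enam an adjusted p of 0.264, the highest over 12 alternatives. The log2 fold change of enam lay between -14.27 and -13.43 in all of them. With 0 UMIs in both mutant libraries this size is set by how a fit treats a count of 0. Its narrow range is therefore no check, and the bounds against the floor of 3 UMIs limit the size of the fall. Fits that leave out a library have genotype as the only term, so stage and genotype are unbalanced and their values and counts carry part of the stage effect. The call count was 39 without the wild-type library labelled 5.8 mm, 3 without the mutant labelled 5.8 mm, 38 without the wild type labelled 7.0 mm, and 20 without the mutant labelled 7.0 mm.

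**Figure D2:**
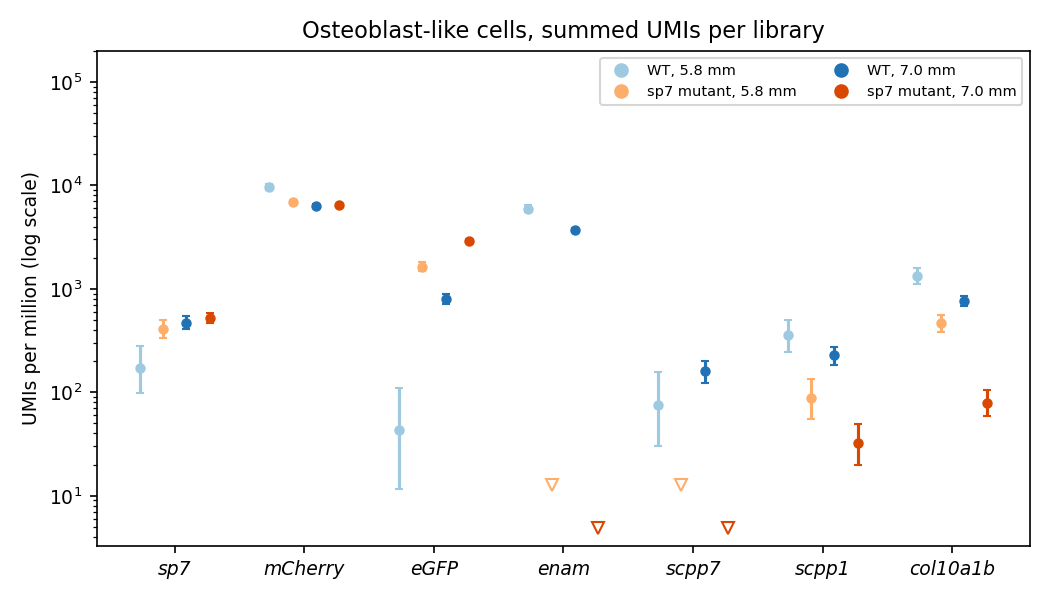
CPM (log scale) of sp7, the reporters mCherry and eGFP, enam, scpp7, scpp1 and col10a1b in osteoblast-like cells of the 4 libraries, with exact Poisson 95% intervals that cover counting error only. Open triangles are libraries with 0 UMIs, drawn at the CPM of 3 UMIs, and enam stood at 5970.5 and 3686 CPM in the wild-type libraries.

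In chondrocyte-like cells, 3 chaperone genes fell and hmgn2 rose in the mutants. The chaperone genes hsp70l, dnajb1b and hsp90aa1.2 fell by 1.79, 1.28 and 0.95 on the log2 scale (standard errors 0.28, 0.23 and 0.15, adjusted p = 0.000124, 0.000537 and 0.000124). The NF-kB inhibitor gene nfkbiaa fell by 1.43 (standard error 0.25, adjusted p = 0.000488), with 227, 430, 273 and 80 UMIs. The nucleosome-binding gene hmgn2 rose by 1.75 (standard error 0.30, adjusted p = 0.000488), with 16, 549, 304 and 513 UMIs. The embryonic globin genes hbae5, hbbe2, hbae1.3 and hbbe1.3 also passed, with hbbe2 at 0, 7, 44 and 1379 UMIs. The erythrocyte-like share of the cells in the mutants was 1.81 and 1.37 times that in wild type at 5.8 mm and 7.0 mm, but 1.35 (0.288 to 8.35) and 0.607 (0.451 to 0.811) with the strict cell filter. In all, 5 genes rose and 4 fell among 3282 tested, 7 of the 9 in the same direction in both stages, with 113 genes at an unadjusted p under 0.05.

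Cartilage matrix genes gave no call in chondrocyte-like cells. None of the 21 tested members passed in edgeR or when adjusted over the list alone, and their median log2 ratios were 0.23 and -0.05. From the dissociation stress list 2 of 21 genes fell, and 5 when adjusted over the list alone. From the inflammation list 1 of 6 fell, and 4 of 6 hemoglobin genes rose. Higher values that did not pass included histh1l at 1.44, hmgb2b at 1.27, hmgb2a at 1.18, h2afvb at 1.01 and id2a at 0.92. Lower values that did not pass included tgm2l at -1.24, ucp2 at -0.75, hsp70.3 at -0.72 and cxcl18b at -0.50. The wild-type library labelled 5.8 mm held only 7 of these cells and 96515 UMIs. RLE size factors and the strict cell filter kept all 9 calls. DESeq2 called 4 of the same genes (hsp70l, dnajb1b, nfkbiaa and hmgn2), the fit with genotype as the only term called 0, and Leiden resolution 2, with the larger set of cells, kept only hbbe2. The call count was 27 without the wild-type library labelled 5.8 mm, where nfkbiaa stood at 0.60, 10 without the mutant labelled 5.8 mm, 16 without the wild type labelled 7.0 mm, where hsp70l stood at 0.14, and 11 without the mutant labelled 7.0 mm. Of the 9 calls, 4, 2, 5 and 0 were among these, and dnajb1b, hsp90aa1.2 and hmgn2 in none of the 4 fits, which carry part of the stage effect. Without the mutant labelled 7.0 mm the globin genes hbae5, hbbe2 and hbbe1.3 stood at -1.19, -1.36 and -3.61.

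In fibroblast-like cells, genes passed in both directions. The proteoglycan gene bcan rose by 1.92 on the log2 scale (standard error 0.40, adjusted p = 0.00111), with 1, 90, 54 and 100 UMIs. The matrix gene coch rose by 1.60 (standard error 0.36, adjusted p = 0.00550), and the alcohol dehydrogenase gene adh8a by 1.46 (standard error 0.37, adjusted p = 0.0404). In the mutant labelled 7.0 mm, the 10 cells of 3013 richest in coch held 356 of its 518 UMIs, the 10 richest in bcan held 50 of its 100 UMIs, and coch leads an unnamed cluster of 1472 cells, so these are not shown to be changes of the whole class. The microfibril gene mfap5, which is among the markers of this class, fell by 1.54 (standard error 0.34, adjusted p = 0.00440). At Leiden resolution 2 a cluster led by genes that include mfap5 held 45 of 309, 53 of 574, 833 of 2796 and 606 of 2979 fibroblast-like cells. The fall of mfap5 is thus not separated from the make-up of the class. The globin gene hbae5 rose by 1.51 (standard error 0.38, adjusted p = 0.0294). In all, 8 genes rose and 18 fell among 11271 tested, 20 of the 26 in the same direction in both stages, with 332 genes at an unadjusted p under 0.05.

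Several of the genes that fell in this class are known from other organs. They include apoc1 of lipoproteins (3, 3, 3922 and 25 UMIs), tg of the thyroid (1, 1, 1325 and 17), fabp1b.2 of gut and liver (41111, 4006, 0 and 0) and gh1 of the pituitary (17, 11, 54 and 0). Without cluster 4, an alternative added after the values were seen, 10 genes were called, all 10 among the 26. DESeq2 called 0 genes in this class. The call count was 74 without the wild-type library labelled 5.8 mm, 108 without the mutant labelled 5.8 mm, 1 without the wild type labelled 7.0 mm, and 76 without the mutant labelled 7.0 mm. These fits carry part of the stage effect. The value of 15.42 for fabp1b.2 in the first follows from its stage difference, since the only library labelled 5.8 mm left is mutant, and hbae5 stood at -0.38 in the last.

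Genes of this class that did not pass included hbbe2 (1.37), col10a1a (1.18), ppp1r1c (0.88), krt97 (0.74) and stat2 (0.72) on the higher side. The protease gene pappa2, which acts on insulin-like growth factor binding proteins, stood at -1.27 with an adjusted p of 0.0836. The lower side also held hsd3b7 (-1.14), b2m (-0.85), mid1ip1b (-0.81) and tdh (-0.76). Of the 19 lists only hemoglobin held a called gene, hbae5. Adjusted over the list alone, 4 hemoglobin, 2 hypertrophic cartilage and 1 bone matrix gene rose.

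Over all kept cells edgeR called 0 of 19667 genes for genotype, with 698 at an unadjusted p under 0.05. That is below the share of 0.05 expected with no effect, as are the counts for chondrocyte-like, fibroblast-like and neuron-like cells. DESeq2 called 46 genes, 20 higher and 26 lower. The pituitary hormone genes gh1 (19237, 120, 1305 and 0 UMIs) and cga (2175, 316, 82 and 1) had log2 fold changes of -8.09 and -3.50, with adjusted p of 0.0776 and 0.151. On the higher side stood pvalb9 at 3.60, s100s at 2.58 and pvalb4 at 2.30. The transmitter transporter gene slc6a1b stood at 2.36 with an adjusted p of 0.109, and the neural regulators gsx2 and prdm12b at 3.40 and 2.32. The olfactory receptor gene or115-12, slc25a4 and the muscle kinase gene ckmb stood at 5.18, 2.44 and 1.93, and eGFP at 2.02. The lower side also held cp at -3.67, prss60.1 at -3.41, lypc at -3.01 and enam at -2.74. Smaller falls were those of lhfpl5b at -2.06, akap12a at -2.02, the iridophore gene pnp4a at -1.92 and irg1l at -1.73. None of these passed the test. Sums over all cells also follow the make-up of the libraries. At 7.0 mm a neuron-like cluster led by genes that include gad2 and slc32a1 held 0.965% of wild-type and 2.91% of mutant cells. An unnamed cluster led by fabp7a held 0.878% and 2.09%. The values of neural and pituitary genes are thus not separated from which tissue each library held. Adjusted over the list alone, 1 tooth gene rose and 3 fell, 1 bone matrix gene fell and 3 hemoglobin genes rose. Cartilage matrix genes had medians of 1.82 at 5.8 mm, where the chondrocyte-like share was 4.59 times that in wild type, and -0.26 at 7.0 mm. Within chondrocyte-like cells the median at 5.8 mm was 0.23.

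In 7 other classes with at least 50 cells in each library, 68 genes were called. In macrophage-like cells 16 rose and 10 fell. This class held 52, 98, 123 and 118 cells, but 36, 50, 106 and 101 when genes called in osteoblast-like cells were left out of the clustering. Its calls are thus not separated from its make-up. The lipid-binding gene fabp11a rose by 2.41 on the log2 scale (standard error 0.41, adjusted p = 1.9e-06). The phosphoprotein gene spp1 fell by 2.87 (standard error 0.45, adjusted p = 1.2e-07), and the chemokine gene cxcl8a fell by 1.42. The acid phosphatase gene acp5a, also known from osteoclasts, fell by 1.43 (standard error 0.37, adjusted p = 0.0163), with 45, 32, 235 and 78 UMIs. In lymphocyte-like cells 9 genes rose and 6 fell, among them the serine synthesis gene psph, which fell by 1.62 (standard error 0.33, adjusted p = 0.000545). In epidermis-like cells 3 genes fell, the protease gene prss60.1, the transglutaminase gene tgm1l3 (36, 6, 1460 and 219 UMIs) and the defensin gene defbl1. Glia-like cells gave 2 higher and 8 lower, mucous cell-like cells 4 and 7, and erythrocyte-like cells 2 and 1, the lower one being the zinc finger gene blf. This gene is among the leading genes of a cluster of that class which held 0, 0, 60 and 15 cells, so its fall is not separated from the make-up of the class. Calls went the same way in both stages for 22 of 26 in macrophage-like, 10 of 15 in lymphocyte-like, 4 of 10 in glia-like and 9 of 11 in mucous cell-like cells, and for all in epidermis-like and erythrocyte-like cells. Neuron-like cells gave 0 calls with edgeR, 163 genes at an unadjusted p under 0.05 and 2 calls with DESeq2. DESeq2 called 9 genes over these classes, with 2 higher and 0 lower in macrophage-like and 1 higher and 0 lower in lymphocyte-like cells, so that spp1, cxcl8a, acp5a and psph were not called. Of the rest 3 were lower in epidermis-like and 1 lower in mucous cell-like cells, and the fit with genotype as the only term called 0.

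The comparison of the libraries labelled 7.0 mm with those labelled 5.8 mm cannot be separated from a difference in preparation, since both libraries of a stage appear to share one. Over all cells 1111 genes rose and 722 fell among 19667 tested. The embryonic globin genes hbae3 and hbbe1.3 rose by 9.41 and 9.06 (standard errors 0.55 and 0.76, adjusted p = 0.00104 and 0.00235). The heart muscle genes myl7 and cmlc1 rose from 0 UMIs in both libraries labelled 5.8 mm, and emilin3a likewise. The gut and liver gene fabp1b.2 fell by 9.76 (standard error 0.64, adjusted p = 0.00136), the retinol-binding gene rbp4l fell by 7.67, and the phototransduction gene gngt1 fell by 6.32. The pituitary gene lhb fell by 7.51 and cga fell by 6.10. The call count, in fits on stage alone that carry part of the genotype effect, was 3511 without the mutant labelled 5.8 mm, 92 without the wild type labelled 7.0 mm, and 94 without the mutant labelled 7.0 mm.

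Within the skeletal classes the stage comparison called 11, 273 and 580 genes in osteoblast-like, chondrocyte-like and fibroblast-like cells. In osteoblast-like cells 7 rose and 4 fell with TMM, and 0 and 0 with RLE size factors. The keratin genes krt5 and cyt1 rose by 3.27 and 4.21 (standard errors 0.55 and 0.78, adjusted p = 0.00379 and 0.00808). The embryonic globin gene hbbe2 and the prostaglandin synthase gene ptgdsb.1 rose by 3.57 and 3.52. From 0 UMIs in both libraries labelled 5.8 mm, hbbe1.3, krt17 and mki67 rose to 22 and 49, 29 and 82, and 19 and 64. The adult globin genes hbaa1 and 2 features named hbba1 fell by 3.33, 3.56 and 3.04, and mmp13b fell from 4 and 29 UMIs to 0 and 0. Of the 11 calls 5 are thus globin and 3 keratin genes. Values that did not pass were col12a1a at 2.67, col10a1b at -2.01, mcl1a at -1.37, rpl29 at -1.35, rn7sk at -1.32 and icn at -1.16. In chondrocyte-like cells 125 rose and 148 fell. The genes hsp70l, lpin1, egr2b, col12a1a and krt5 rose by 2.66, 2.89, 2.75, 2.61 and 2.45. The genes nfkbiaa, fn1b, ucp2, the cartilage matrix gene ucmaa and rbp4 fell by 2.84, 2.66, 2.55, 2.48 and 2.37. In fibroblast-like cells 274 rose and 306 fell. The fin fold matrix genes and1 and and2 were at 0 UMIs in both libraries labelled 5.8 mm, with 63 and 380 UMIs for and1 and 343 and 1019 for and2 in those labelled 7.0 mm, as was gem, with 59 and 53. The embryonic globin genes hbbe1.3 and hbae3 rose by 6.54 and 6.45, and fabp1b.2 fell from 41111 and 4006 UMIs to 0 and 0. Few cells carry some of these sums: the 10 richest of 3013 cells of the mutant labelled 7.0 mm held 305 of the 380 and1 UMIs, and the 10 richest of 360 cells of the wild type labelled 5.8 mm held 35815 of the 41111 fabp1b.2 UMIs, 99.8% of which lay in cluster 4. The pteridine synthesis gene gch2 fell by 4.12, fgfbp2a by 3.43, b2m by 3.28 and ppp1r1c by 2.95. Without the wild type 5.8 mm, mutant 5.8 mm, wild type 7.0 mm and mutant 7.0 mm library in turn, the call counts were 66, 100, 25 and 21 in osteoblast-like cells. They were 327, 294, 130 and 127 in chondrocyte-like cells, and 352, 935, 197 and 456 in fibroblast-like cells.

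The globin genes in use ran against the order of the stage labels. Zebrafish replace embryonic by adult globins as they grow. Adult globins made up 98.1%, 90.2%, 4.20% and 12.7% of globin UMIs. Of the erythrocyte-like cells, 87.9% (76.7 to 95.01), 64.2% (55.6 to 72.2), 3.12% (1.79 to 5.02) and 7.10% (5.30 to 9.28) carried mostly adult globin UMIs. These libraries are therefore named by their labels throughout, and no age is inferred.

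**Figure D3:**
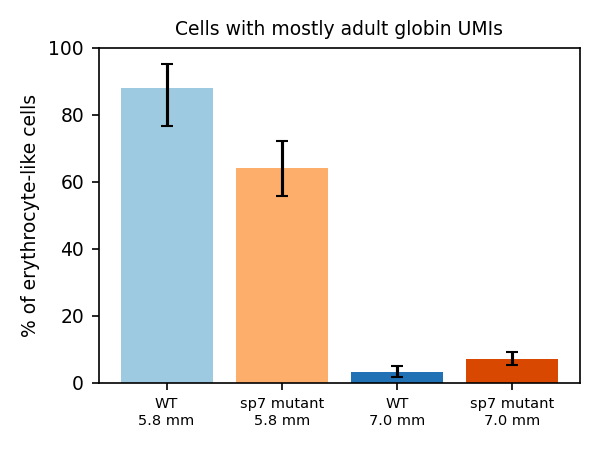
Percent of erythrocyte-like cells whose globin UMIs were mostly adult, as bars from 0 with exact Clopper-Pearson 95% intervals, for the 4 libraries. The libraries labelled 5.8 mm stood at 87.9% and 64.2%, and those labelled 7.0 mm at 3.12% and 7.10%.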

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

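The tests of enam depth, of enam in epidermis-like cells, of free globin RNA and both tests of the organ genes were chosen only after the result was seen. Those of the enam-carrying subset and of exchanged stage labels were set down before their values were seen.

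The mCherry reporter in fibroblast-like cells went opposite ways at the 2 stages. Its mutant to wild-type ratio was 0.301 at 5.8 mm and 1.56 at 7.0 mm, from 18, 8, 148 and 257 UMIs. The difference between the stages was not tested.

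No enam UMI was counted in mutant osteoblast-like cells. Fewer sampled UMIs are argued against by depth, since the wild-type level predicts 1411 UMIs in the mutant labelled 5.8 mm and 2288 in the one labelled 7.0 mm. A deleted or uncountable enam gene is argued against by epidermis-like cells, where the mutant labelled 7.0 mm had 104 CPM against 58.8 in wild type, and both mutants together held 560 UMIs. Loss of an enam-carrying subset of cells and loss of the transcript within cells cannot be told apart: 30 genes picked in enam-carrying wild-type cells had a median log2 ratio of -0.10 (-0.21 to 0.01), against -0.16 (-0.24 to -0.09) when those cells are removed. Whether Sp7 acts on enam itself within these cells stays open and was not tested. Removing any Sp7 binding sites near enam in wild type would bear on it.

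Adult globin marked the libraries labelled 5.8 mm. Free globin RNA is argued against, since 64.2% and 87.9% of their erythrocyte-like cells carried mostly adult globin, against at most 7.10% at 7.0 mm. Exchanged stage labels could give this pattern, and if the tags in the file names are dates, the pair labelled 5.8 mm was prepared a week after the pair labelled 7.0 mm. The test with 3 B cell genes, which appear late in larval life, left it open. They stood at 0.356 and 1.02 CPM in the libraries labelled 5.8 mm and 0.305 and 0.279 in those labelled 7.0 mm. These values rest on 8, 24, 10 and 9 UMIs, and 20 of the 24 were pax5, so the counts are too few to decide it. The gene ighm, also named for this test, is not among the 3. A difference in preparation or in age, both confounded with stage, also stays open.

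Genes of other organs were lower in mutant fibroblast-like cells. A few cells of other organs within cluster 4 may be a source for some of them, since 10 of the 26 calls were still made without that cluster. In that fit 7 genes (tg among them) were not testable, and 5 of the 18 lower calls, including the class marker mfap5, were among the 10. At Leiden resolution 2 an unnamed cluster of 17 cells, with apoa2, fabp10a and apoc1 among its leading genes, held 1, 0, 16 and 0 cells. Where these cells lay at the resolution used for the classes was not examined. Cells of cluster 4 are not the whole source, because gh1, with 11.1% of its UMIs there, went only from -2.98 (standard error 0.54) to -2.79 (0.60) on the log2 scale. Likewise apoc1 and fabp1b.2, at -6.77 and -4.11, stayed called at -2.23 (0.55) and -2.59 (0.57) with adjusted p of 0.0469 and 0.0140. By contrast gapdh went from -2.83 to -0.13, gamt from -1.46 to 0.26, c8g from -2.37 to -0.76 and cox8b from -1.83 to -0.73. No longer called but little changed were igfbp1a (-1.62 to -1.44) and acta2 (-1.89 to -1.88). Free RNA is argued against as the main source over the whole class, because the 10 richest cells held a median of 83.5% of a lower gene's UMIs, and over 50% for 16 of the 18. The apoc1 and fabp1b.2 UMIs outside cluster 4 are not covered by this, since 97.2% and 99.8% of those counted lay in that cluster. Free RNA stays open for them. A difference between dissections stays open, and no biological explanation was tested.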

How the results depend on the processing

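The fits without erythrocyte-like cells, with other variable genes for the differential tests, outside cluster 4, and for the other classes were chosen after seeing the data, and the cause of no change was tested. For genotype over all cells (0 calls), DESeq2 gave 46, no filter 61, the strict cell filter 19 and no erythrocyte-like cells 1, with 0 to 0 when each library was left out. In osteoblast-like cells (9), RLE gave 2, DESeq2 3, no filter 21, 1 term 2, the strict filter 17, resolution 2, the bone lists and the list without called genes 2 each, and leaving out a library 3 to 39. In chondrocyte-like cells (9), DESeq2 gave 4, no filter 22, 1 term 0, resolution 2 gave 1, and leaving out a library 10 to 27. In fibroblast-like cells (26), DESeq2 and 1 term gave 0, no filter 167, resolution 2 gave 7, the bone lists 11, no called genes 9, outside cluster 4 10, and leaving out a library 1 to 108. Other classes (68) gave 9 with DESeq2 and 0 with 1 term. For stage, all cells gave 1051 with doublets kept and 92 to 3511 without a library. Osteoblast-like cells gave 0 with RLE, 2 with DESeq2, 34 with no filter, 3 with 1 term, 20 with the strict filter, 2 with the bone lists and 21 to 100 without a library. Chondrocyte-like cells gave 83, 82, 127 and 166 with DESeq2, no filter, 1 term and resolution 2, and 127 to 327 without a library. Fibroblast-like cells gave 106 with DESeq2, 359 with 1 term and 197 to 935 without a library.

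Fits without a library used 1 term on 3 libraries, so that 2 choices change together. They leave stage and genotype unbalanced, carry part of the other factor's effect and assume that the lone library varies like the others, so changed signs in them are not read as dependence on a library. Without the wild type labelled 5.8 mm the log2 fold change turned for col1a2 (range over these fits -1.91 to 0.0191) and mCherry (-0.92 to 0.20) in osteoblast-like cells, nfkbiaa (-3.395 to 0.60) in chondrocyte-like cells and fabp1b.2 (-19.47 to 15.42) in fibroblast-like cells. Without the mutant labelled 7.0 mm it turned for hbbe1.3 (-3.61 to 8.84), hbae5 (-1.19 to 11.52) and hbbe2 (-1.36 to 11.80) in chondrocyte-like cells, and for hbae5 (-0.38 to 4.08) and and1 (-7.19 to 9.63) in fibroblast-like cells. Without the wild type labelled 7.0 mm it turned for hsp70l (-3.64 to 0.14) in chondrocyte-like cells, and for gapdh (-3.75 to 2.21) and gamt (-2.26 to 0.14) in fibroblast-like cells. The bone lists gave gapdh 0.15 and gamt 0.28, resolution 2 gave gamt 0.15, and outside cluster 4 it was 0.26. Of the other values for called genes, outside the fits that leave out a library, 28 of 64 kept direction and call in osteoblast-like cells, 39 of 72 in chondrocyte-like and 88 of 185 in fibroblast-like cells.

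The chondrocyte-like ratio at 5.8 mm was 1.62 with the bone lists and 2.68 at resolution 2, and the fibroblast-like ratio 1.09 without called genes. The enam bound at 5.8 mm was 587 with TMM-scaled CPM. Without thinning, sp7 shares were 42.1%, 71.4%, 59.3% and 70.202%, and eGFP shares at 7.0 mm 32.9% and 71.7%. The eGFP level of the mutant labelled 5.8 mm was 1893 CPM with the strict filter. The counts of 7 chondrocyte-like and 19 osteoblast-like cells in the wild type labelled 5.8 mm limit what depth can show there.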

Other observations

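No tests are added here, and the values below were chosen after they were seen. The enamel-type transcripts were also counted outside the osteoblast-like cells. In epidermis-like cells enam had 59, 44, 303 and 516 UMIs in wild type 5.8 mm, mutant 5.8 mm, wild type 7.0 mm and mutant 7.0 mm, and scpp7 had 3232, 4115, 63 and 476. The eGFP reporter was also counted in endothelial-like cells, at 0, 38, 139 and 48 UMIs. Of all eGFP UMIs, 5.26%, 75.6%, 39.5% and 71.1% lay in osteoblast-like cells, as did 16 of 32, 97 of 163, 208 of 360 and 325 of 502 sp7 UMIs.

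Some unnamed clusters also differed between the stage labels. A cluster with col8a2, sost and pax1b among its top genes held 0.188%, 0.0720%, 5.69% and 4.16% of the cells. One with col4a3 and foxq1b held 0.494%, 0.144%, 2.90% and 2.35%, and a cycling one with dlx4a held 0.0941%, 0.0900%, 1.296% and 1.80%. A cluster with grn2, spic and il1fma held 0.541%, 0.738%, 0.322% and 0.417%, with intervals that overlap between the stages within each genotype.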
